A study of Mus musculus with 7 samples.

How the data were processed

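RNA from microdissected mouse kidney tissue of embryonic day 12.5 and from a subclone of mIMCD-3 cells was hybridised to Affymetrix mouse genome arrays. Per the labels, total RNA was extracted with RNeasy columns and DNase, and 1 ug went into labelling as biotinylated cRNA. The 7 arrays comprise 2 of metanephric mesenchyme, 2 of ureteric bud stalk, 2 of ureteric bud tip and 1 of mIMCD-3. The 6 tissue arrays had been published before, and the authors recalculated robust multichip analysis (RMA) values over all 7 arrays together. RMA corrects the background, equalises the distributions of probe signals between arrays and summarises each probe set. Its software and version are not stated in the sources used here. The deposited values are intensity on a linear scale, from 5.08 to 19587, and they were converted to log2 here. Because mIMCD-3 was hybridised later than the tissues and has a single array, its cell line and its batch cannot be told apart. RMA gives no detection calls, and folds of dim genes are compressed.

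The table holds 45101 probe sets, of which 64 are controls. Of the probe sets, 34945 list exactly 1 gene, 932 list several and 9160 list none. For each of 18193 genes, the probe set with the highest mean over all arrays was used, and 9010 genes had more than 1. Gene symbols come from the array annotation, and 99.4% of its Entrez identifiers were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. No gene was filtered out.

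The tissues were compared with limma 3.58.1 in R 4.3.3, in 1 fit of the 6 tissue arrays with a coefficient per group and 3 residual degrees of freedom. The fit shares the spread of a gene between the groups, although the groups differed in spread. Across probe sets, the standard deviation of replicate 1 minus replicate 2 was 0.26 in mesenchyme, 0.19 in stalk and 0.35 in tip. The contrasts were the mean of tip and stalk against mesenchyme, stalk against mesenchyme, tip against mesenchyme, and tip against stalk. For the mean of tip and stalk, the standard error reflects the spread within groups and not the difference between tip and stalk. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Tests were two-sided. mIMCD-3 was not part of the fit, and its differences were described by size only, with percentiles among 10000 random lists matched in size and in 20 bins of brightness. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

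A set of 24 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment within a contrast, for bud against mesenchyme and for tip against stalk. The lists are tight junction and apical polarity, adherens junction and desmosome, epithelial keratins and splicing regulators, epithelial transcription factors, mesenchymal state, nephron progenitor, renal stroma, early nephron epithelium, ureteric bud tip, ERK signalling response, ureteric stalk and urothelium, collecting duct transport, canonical Wnt targets, basement membrane and epithelial integrins, interstitial matrix, cell cycle, hypoxia and glycolysis, immediate early genes, endothelium, erythroid cells, myeloid cells, neurons and neural crest, smooth muscle, and sex-linked genes. They hold 366 distinct genes, and 347 of 367 entries were measured, 1 of them (Ccn1) through an older symbol. For stalk or tip alone against mesenchyme only counts and medians of the lists are given. The sex-linked list joins Xist with Y-linked genes, so its median and its call do not stand for a direction of sex. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule named the 10 genes with the largest and the 10 with the smallest difference per contrast among those called whose arrays do not overlap between the sides. It further named up to 4 members per list with the largest absolute difference, the genes Cdh1, Grhl2, Vim, Six2, Ret, Wnt11 and Wnt7b, and the 8 highest and 8 lowest genes of mIMCD-3 against bud by the size rule. Genes without a name were passed over. The text names a subset of these, and S100a4 and other genes in the closing section were chosen after their values were seen.

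Of 187 genes named by the rule, 108 have more than 1 probe set. For 26 of them the probe sets differ in sign between bud and mesenchyme, and for 23 between tip and stalk.

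Arrays of the same replicate number were checked for pairing, which the labels do not state. The differences of replicate 1 minus replicate 2 correlated across probe sets at 0.39 between mesenchyme and stalk, 0.57 between mesenchyme and tip and 0.43 between stalk and tip. All 3 exceeded 0.1, the value set for treating the numbers as pairs, so a fit with the replicate number as a block (2 residual degrees of freedom) was run as an alternative. Values given without naming the block come from the fit without it. A deviation shared by arrays of the same number stays in their residual spread. Quality was described by control probe sets. The log2 difference between 3′ and 5′ probe sets lay between -0.17 and 0.02 for Gapdh and between 0.30 and 0.40 for beta-actin. The 18 hybridisation control sets of tip replicate 2 lay at -0.57 relative to the mean of all 7 arrays, against 0.01 to 0.19 in the remaining 6.

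The other alternatives were the mean of all probe sets of a gene, every probe set on its own, leaving out probe sets that may cross-hybridise by their name, leaving out the 40% of genes with the lowest mean, a trend and robust variance in limma, centring each array on its median, quantile normalization over the 6 tissue arrays, a minimum change of 1 log2 unit, an estimated inter-gene correlation, fitting only the arrays of the 2 groups compared, steps of 1 or 2 log2 units for mIMCD-3, and leaving out each array in turn.

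The procedure was tested on simulated data with 200 changed genes among 18193, 50 of each size, raised or lowered, and without pairing of arrays. At 0.5 log2 units limma called 16% of them for bud against mesenchyme, 12% for stalk against mesenchyme, 14% for tip against mesenchyme and 8% for tip against stalk. At 1 log2 unit it called 100%, 98%, 96% and 94% in the same order, and at 2 and 3 log2 units 100% in each. Among all calls, 6.51%, 7.74%, 5.49% and 5.03% were unchanged genes. A simulated list of 15 genes raised by 1 log2 unit was called in each contrast with the preset correlation. With an estimated correlation its adjusted p was 0.0349 for bud against mesenchyme, 0.0521 for stalk against mesenchyme, 0.434 for tip against mesenchyme and 0.0511 for tip against stalk, and 0 unchanged lists were called with either correlation in any contrast. The simulated genes were independent, so this setting can miss a raised list whose members are not correlated. In the data, the erythroid list lost its call for bud against mesenchyme at an estimated correlation of -0.048, below the preset 0.01. A call lost with an estimated correlation is therefore no evidence by itself that the members of a list are correlated. Across the lists the estimates ran from -0.056 for keratins and splicing regulators to 0.70 for sex-linked genes. They were 0.50 for nephron progenitor and 0.48 for renal stroma. Where the estimate is this high, an adjusted p at the preset correlation may be too small.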

Results

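Gene expression was measured on 7 Affymetrix mouse arrays. At E12.5, the embryonic stage studied, the kidney forms where the ureteric bud, an epithelial tube, branches into the metanephric mesenchyme, a non-epithelial tissue. Metanephric mesenchyme, ureteric bud stalk and ureteric bud tip were each represented by 2 biological replicate arrays. A single array held a subclone of mIMCD-3, a cell line from the mouse inner medullary collecting duct, grown to confluency. The median probe set intensity lay between 45.7 and 49.2 in the 6 tissue arrays and was 42.1 in mIMCD-3. Replicate arrays correlated across probe sets at r = 0.994 in mesenchyme, 0.997 in stalk and 0.990 in tip. Probe sets are not independent replicates, and the small number of arrays limits the precision of every value. Between group means, the correlation was 0.987 for mesenchyme and stalk, 0.968 for mesenchyme and tip, 0.982 for stalk and tip, and 0.899 to 0.919 for mIMCD-3 with the tissues. Values are log2 intensities, and differences are in log2 units with the standard error of the limma fit.

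The comparison of ureteric bud with metanephric mesenchyme asked which genes separate epithelial from non-epithelial renal tissue. Cdh1, which encodes the adherens junction protein E-cadherin, was 6.91 ± 0.13 (SE) higher in the 4 bud arrays than in the 2 mesenchyme arrays, with means of 3.84 in mesenchyme, 10.47 in stalk and 11.03 in tip (adjusted p = 3.42e-07). Its mesenchyme mean lay below the lower quartiles of the mesenchyme arrays (4.06 and 4.17), so the exact size of this difference is uncertain. The calcium-binding protein gene Calb1 was 7.18 ± 0.19 higher, and the claudin gene Cldn8 was 6.44 ± 0.11 higher. Mal2, whose product acts in apical transport, was 6.12 ± 0.14 higher, Esrp1, an epithelial splicing regulator, 5.58 ± 0.13 higher and the keratin gene Krt8 5.32 ± 0.10 higher. Grhl2, a transcription factor gene of epithelia, was 3.66 ± 0.12 higher (adjusted p = 2.5e-06). In all, 1116 of 18193 genes were higher in bud and 902 were lower, of which 560 and 363 differed by at least 1 log2 unit.

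Genes of epithelial junctions were higher in bud as a group. Of 27 tight junction and apical polarity genes measured, 20 were higher and 0 lower (21 and 0 adjusted over the list alone), with a median of 1.68. Cldn4 (5.56), Cldn6 (5.29) and Ocln (5.19) had some of the largest differences. The list was called in the gene list test (adjusted p = 1.01e-26), but not with an inter-gene correlation estimated from the arrays (adjusted p = 0.0556 with an estimated correlation). Among 21 adherens junction and desmosome genes, 16 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median of 2.71 and examples in Cdh16 (5.25), Epcam (4.97) and the desmoplakin gene Dsp (4.18). Each of the 7 epithelial keratins and splicing regulators was higher (7 adjusted over the list alone), with a median of 4.27, including Krt18 (5.20) and Krt7 (4.27). These 2 lists were called with the preset correlation (adjusted p = 2.9e-22 and 5.16e-17) and with an estimated correlation (adjusted p = 0.0368 for both). Of 18 epithelial transcription factor genes, 14 were higher and 0 lower, also when adjusted over the list alone, with a median of 2.16. Tfcp2l1 (5.48), Emx2 (4.65) and Gata3 (4.19) led this list (adjusted p = 5.87e-20, and adjusted p = 0.0539 with an estimated correlation).

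**Figure D1:**
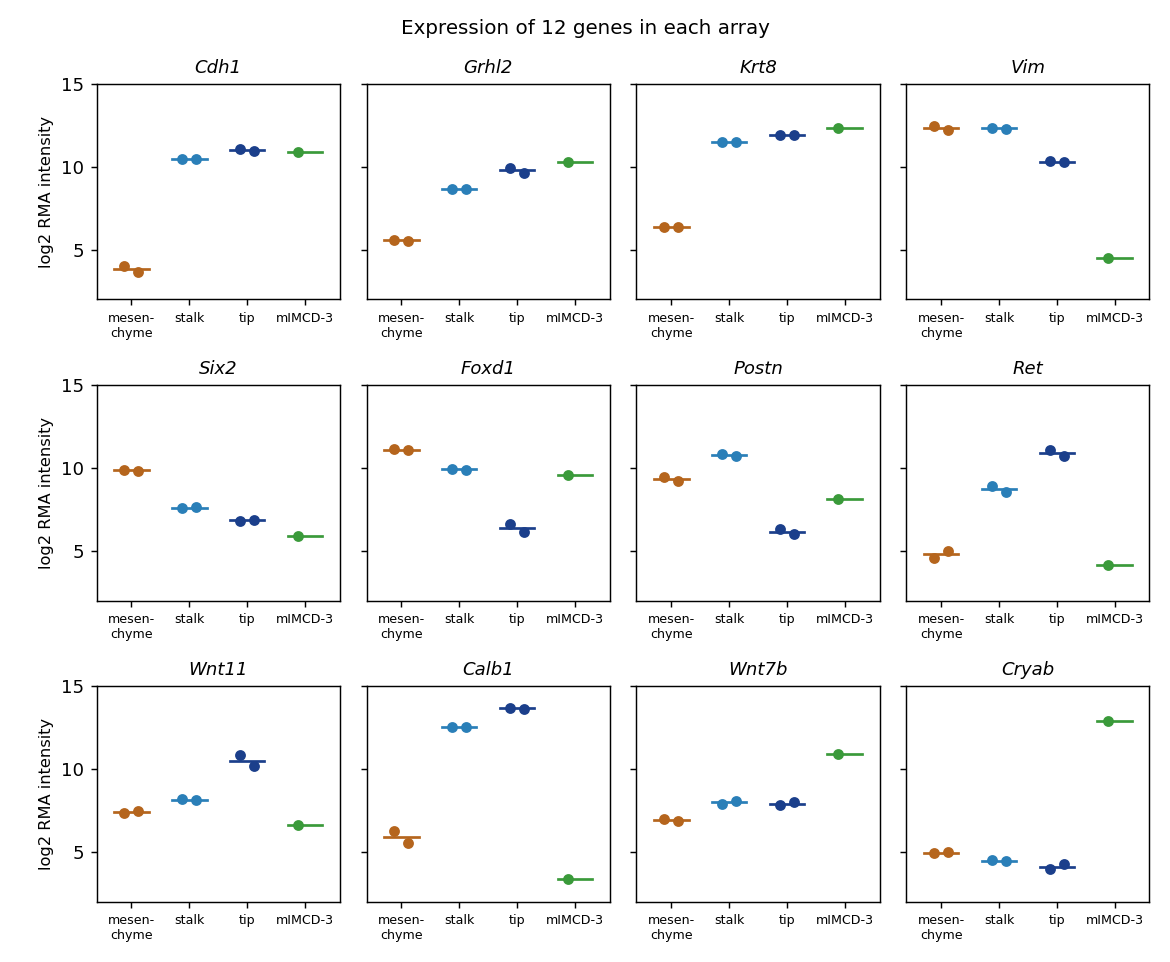
Log2 RMA intensity of 12 genes in each array. Points are single arrays and lines are group means, over 2 arrays per tissue and 1 mIMCD-3 array, and Cdh1 lies at 3.84 in mesenchyme against 10.47 in stalk, 11.03 in tip and 10.88 in mIMCD-3.

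Genes of the nephron progenitors of the mesenchyme were lower in bud. All 13 measured members were lower, also when adjusted over the list alone, with a median of -2.31 (adjusted p = 1.29e-21, and adjusted p = 0.0703 with an estimated correlation). Six2, the progenitor transcription factor gene, had a difference of -2.64 ± 0.10 (adjusted p = 5.36e-06). Eya1, Meox1 and Crym had differences of -3.28, -3.22 and -3.17. The lowest values of the comparison belonged to the arginase gene Arg1 (-3.81 ± 0.16) and the homeobox gene Meox2 (-3.70 ± 0.14). The retinoic acid binding protein gene Crabp1 (-3.37) and the R-spondin genes Rspo3 (-3.33) and Rspo1 (-3.22), whose products enhance Wnt signalling, were lower as well. Of 15 renal stroma genes, 12 were lower and 1 was higher (13 and 1 adjusted over the list alone), with a median of -1.17 and a difference of -2.94 for the stromal transcription factor gene Foxd1 (adjusted p = 4.8e-13, and adjusted p = 0.0868 with an estimated correlation). Of 14 genes of the mesenchymal state, 10 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -0.99 (adjusted p = 1.61e-11, and adjusted p = 0.0703 with an estimated correlation). The N-cadherin gene Cdh2 had a difference of -2.39. The vimentin gene Vim had one of -1.04 ± 0.12 (adjusted p = 0.000907), a mean over stalk, where it was not called, and tip, where it was lower. Against mesenchyme, the medians of the stroma, mesenchymal state and interstitial matrix lists were 0.19, 0.08 and 0.30 in stalk. In tip they were -2.96, -2.38 and -1.36, so the lower bud values of these lists came mainly from the tip. Of 18 interstitial matrix genes, 10 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.63 and -1.69 for Col1a1 (adjusted p = 2.48e-08, and adjusted p = 0.0556 with an estimated correlation). Without mesenchyme replicate 1, 0 stroma genes were higher.

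Lists of bud identity and of signalling were higher in bud with the preset correlation and were not called with an estimated correlation. For the ureteric bud tip list, 8 of 9 genes were higher and 0 lower (8 and 1 adjusted over the list alone; median 1.61; adjusted p = 2.02e-10, and adjusted p = 0.0868 with an estimated correlation). Ret, the receptor gene for the growth factor GDNF, was 5.01 ± 0.18 higher, and Wnt11, a tip ligand gene, was 1.90 ± 0.18 higher. Of 11 canonical Wnt targets, 8 were higher and 0 lower (9 and 1 adjusted over the list alone; median 0.89), with Rnf43 at 2.24 (adjusted p = 9.9e-07, and adjusted p = 0.0868 with an estimated correlation). Of 12 ureteric stalk and urothelium genes, 5 were higher and 0 lower, also when adjusted over the list alone (median 0.11; adjusted p = 2.61e-05, and adjusted p = 0.065 with an estimated correlation). Besides Calb1, these included Wnt9b (3.05), Shh (2.26) and the ligand gene Wnt7b (1.03 ± 0.12; adjusted p = 0.00126). Of 21 basement membrane and epithelial integrin genes, 8 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.19), led by the laminin gene Lama1 at 2.52 (adjusted p = 1.64e-05, and adjusted p = 0.0868 with an estimated correlation). Of 16 ERK signalling response genes, 5 were higher and 1 lower (7 and 2 adjusted over the list alone; median 0.25), with Myb at 2.01 (adjusted p = 0.000493, and adjusted p = 0.315 with an estimated correlation). Without mesenchyme replicate 2 the higher count of the ERK list was 2, without mesenchyme replicate 1 or either stalk array it was 3, and without tip replicate 1 the tip list had 1 gene lower.

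Among 17 collecting duct transport genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.12), with the sodium channel subunit genes Scnn1g at 2.93 and Scnn1b at 1.78. This list was called (adjusted p = 0.00412), and it was not called with an estimated correlation (adjusted p = 0.239) or without the dimmest 40% of genes (adjusted p = 0.0605). Of 15 hypoxia and glycolysis genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; median 0.26), with the glucose transporter gene Slc2a1 at 0.94 (adjusted p = 0.00104, and adjusted p = 0.0868 with an estimated correlation). The higher count was 1 without mesenchyme replicate 2 and 7 with trend and robust variance. Of 16 immediate early genes, 7 were higher and 1 lower (9 and 3 adjusted over the list alone, 9 and 4 with the replicate block; median 0.39), with Klf6 at 1.19 and Klf2 at -1.24 (adjusted p = 0.00302, and adjusted p = 0.342 with an estimated correlation). Without mesenchyme replicate 2 the higher count was 3, without mesenchyme replicate 1 or either stalk array it was 4, and without tip replicate 1 the lower count was 3. In the early nephron epithelium list, 4 of 13 genes were higher and 5 lower (4 and 7 adjusted over the list alone). Its median of -0.32 and mean of 0.20 differed in sign, and the list was not called (adjusted p = 0.504). Its Lhx1 was 3.52 higher and its Jag1 1.75 higher. The higher count was 2 without mesenchyme replicate 2 or stalk replicate 1, and the lower count was 1 without mesenchyme replicate 1 and 2 without mesenchyme replicate 2 or either stalk array. Of 28 cell cycle genes, 0 passed in the limma fit without a block, 1 was higher and 1 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. With the replicate block 1 passed as lower (Ccne1; adjusted p = 0.0197), and with trend and robust variance 1 passed as higher and 2 as lower. The cell cycle median of -0.01 and mean of 0.01 differed in sign, and the list was not called (adjusted p = 0.699).

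Markers of other cell types were lower in bud than in mesenchyme. Of 15 endothelium genes, 12 were lower and 0 higher (14 and 0 adjusted over the list alone; median -1.13), with Ramp2 at -1.65 and Plvap at -1.63 (adjusted p = 3.4e-15, and adjusted p = 0.0556 with an estimated correlation). Of 8 erythroid cell genes, 5 were lower and 0 higher (6 and 0 adjusted over the list alone; median -0.84), with the embryonic globin gene Hbb-bh1 at -2.08 (adjusted p = 1.87e-06, and adjusted p = 0.0556 with an estimated correlation). Of 12 myeloid cell genes, 7 were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.80), with the complement gene C1qa at -1.84 (adjusted p = 5.37e-07, and adjusted p = 0.0868 with an estimated correlation). Without mesenchyme replicate 1 the lower count was 4, and without mesenchyme replicate 2 the higher count was 0. Of 11 genes of neurons and neural crest, 3 were lower and 0 higher (7 and 0 adjusted over the list alone, 8 and 0 with the replicate block; median -0.38), with Elavl4 at -1.97 (adjusted p = 6.83e-05, and adjusted p = 0.0703 with an estimated correlation). Of 6 smooth muscle genes, 3 were lower and 0 higher, also when adjusted over the list alone (median -0.51; adjusted p = 0.000309, and adjusted p = 0.0868 with an estimated correlation). Of 4 sex-linked genes, 0 passed in the limma fit without a block, 1 was lower at an unadjusted p under 0.05, when adjusted over the list alone and with the replicate block, and the list had a median of -0.31 (adjusted p = 0.211). Without ureteric bud tip replicate 1 the list was called (adjusted p = 0.0275) with 1 gene lower.

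The number of genes called in this comparison changed with the block and with the arrays left out. Leaving out an array by design lowers the precision of contrasts with its group, so fewer calls need not point to that array. With the replicate number as a block, 1655 genes were higher and 1552 lower. Without mesenchyme replicate 1 the lower count was 475, and without mesenchyme replicate 2 the higher count was 725.

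The stalk was compared with the mesenchyme on its own. Cdh1 was 6.63 ± 0.15 higher in the 2 stalk arrays than in the 2 mesenchyme arrays (adjusted p = 1.34e-06), Calb1 was 6.62 ± 0.22 higher and Cdh16, the kidney-specific cadherin gene, was 5.34 higher. Ret was 3.92 ± 0.21 higher, Grhl2 3.10 ± 0.14 higher and Wnt7b 1.07 ± 0.14 higher. Vim lay at 12.34 in mesenchyme and 12.31 in stalk (difference -0.03 ± 0.14; adjusted p = 0.969). Wnt11 had a difference of 0.73 ± 0.21, which did not pass (adjusted p = 0.126). It passed with the replicate block (adjusted p = 0.0354), with trend and robust variance (adjusted p = 0.011) and with arrays centred on their medians (adjusted p = 0.0426). Wnt11 also passed without either tip array. These settings are the same fit for this contrast, because a single tip array adds no residual spread. The progenitor genes Meox1 (-2.87), Crym (-2.29), Six2 (-2.26 ± 0.12) and Eya1 (-2.17) were lower in stalk, as were Arg1 (-2.81) and the netrin gene Ntn1 (-2.17).

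In this comparison 782 genes were higher in stalk and 225 lower. Fitted on the stalk and mesenchyme arrays alone, 922 were higher and 316 lower. Of the adherens junction and desmosome list 13 genes were higher (15 adjusted over the list alone), of the tight junction list 19, of the epithelial transcription factors 14 and of the keratins and splicing regulators 7, and 0 genes of these lists were lower. In the nephron progenitor list 9 of 13 genes were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -1.68. The renal stroma list, by contrast, had 4 genes higher, 4 lower and 7 not called (6 higher and 5 lower adjusted over the list alone), with a median of 0.19. The mesenchymal state list had 2 higher and 2 lower of 14, with a median of 0.08 and a mean of -0.04, which differ in sign. In the interstitial matrix list 3 of 18 genes were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.30. In the early nephron epithelium list 4 of 13 genes were higher and 0 lower (6 and 2 adjusted over the list alone), and its median of -0.07 and mean of 0.41 differed in sign. Endothelium genes had a median of -0.58 with 5 of 15 lower and 0 higher (12 and 0 adjusted over the list alone). Of 16 immediate early genes, 8 were higher in stalk and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.64.

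The counts for stalk against mesenchyme were 1231 higher and 577 lower with the replicate block. They were 427 and 96 without stalk replicate 1, and 473 and 92 without stalk replicate 2. Without mesenchyme replicate 2 they were 491 and 138, and without mesenchyme replicate 1 the lower count was 93.

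The tip was compared with the mesenchyme in the same way. Cdh1 was 7.19 ± 0.15 higher in the 2 tip arrays (adjusted p = 7.3e-07), Calb1 7.74 ± 0.22 higher, Ret 6.10 ± 0.21 higher and Aldh1a1, a gene for an enzyme of retinoic acid synthesis, 5.95 ± 0.19 higher. Grhl2 was 4.22 ± 0.14 higher, Wnt11 3.07 ± 0.21 higher and Wnt7b 0.99 ± 0.14 higher. Vim was lower in tip (-2.04 ± 0.14; adjusted p = 3.83e-05), and so was Six2 (-3.03 ± 0.12). The lowest values belonged to Meox2 (-4.89 ± 0.16), Rspo3 (-4.85 ± 0.13), Crabp1 (-4.85 ± 0.18), Arg1 (-4.82 ± 0.18) and Foxd1 (-4.71 ± 0.17). In total 1342 genes were higher in tip and 1523 lower. Fitted on the tip and mesenchyme arrays alone, 1109 were higher and 1289 lower.

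Of the renal stroma list 13 of 15 genes were lower in tip and 0 higher (14 and 0 adjusted over the list alone; median -2.96). Of the mesenchymal state list 13 of 14 were lower (13 adjusted over the list alone; median -2.38), of the nephron progenitor list 12 of 13 (13 adjusted over the list alone; median -3.07), and of the interstitial matrix list 16 of 18 (16 adjusted over the list alone; median -1.36), with 1 matrix gene higher. The ERK signalling response list had 10 of 16 genes higher and 1 lower (11 and 1 adjusted over the list alone). The immediate early genes had 4 of 16 higher and 5 lower (6 and 5 adjusted over the list alone), with a median of 0.13 and a mean of -0.003 on opposite sides of 0. Endothelium genes had a median of -1.69 with 12 of 15 lower and 0 higher (14 and 0 adjusted over the list alone). With the replicate block 2037 genes were higher and 2331 lower, and without mesenchyme replicate 1 the lower count was 987.

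**Figure D2:**
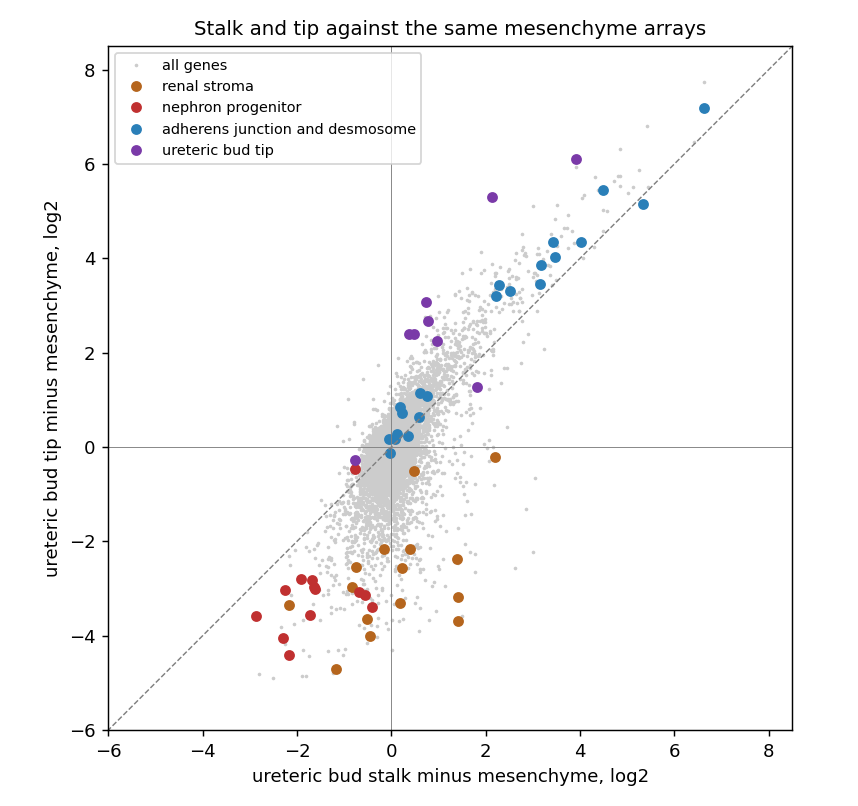
Difference from mesenchyme in stalk (horizontal axis, log2) and in tip (vertical axis, log2) for all genes, with the members of 4 lists in colour and a dashed line where both are equal. Renal stroma genes have a median of 0.19 in stalk and -2.96 in tip, and nephron progenitor genes have medians of -1.68 and -3.07.

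Tip and stalk, both from the ureteric bud, were compared with each other to find what distinguishes the branching tips from the stalk. Slco4c1, an organic anion transporter gene, was 3.15 ± 0.27 higher in tip. Wnt11 was 2.34 ± 0.21 higher (means 10.50 and 8.16; adjusted p = 0.000424) and Ret 2.18 ± 0.21 higher (means 10.88 and 8.70; adjusted p = 0.000599). Etv4, a transcription factor gene downstream of Ret signalling, was 2.04 ± 0.13 higher. Of the ureteric bud tip list 7 of 9 genes were higher in tip and 0 lower (8 and 1 adjusted over the list alone; median 1.92), among them Sox8 (2.03) and Ros1 (1.91). The list was called (adjusted p = 1.06e-07, and adjusted p = 0.182 with an estimated correlation). Of 16 ERK signalling response genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone; median 0.76), with Etv5 at 2.02, Myb at 1.68 and the feedback inhibitor gene Spry1 at 1.51 (adjusted p = 4.68e-06, and adjusted p = 0.228 with an estimated correlation). The lower count of the ERK list was 0 without any single array other than tip replicate 1.

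Among the genes lower in tip were those of stroma and matrix. Plcxd3 was 37.4-fold lower in tip than in stalk (-5.23 ± 0.23), the cardiac actin gene Actc1 36.4-fold (-5.18 ± 0.13) and Tbx18, a transcription factor gene of ureteric mesenchyme, 34.1-fold (-5.09 ± 0.29). The matrix protein gene Postn had a difference of -4.60 ± 0.16 and Foxd1 one of -3.53 ± 0.17. All 15 renal stroma genes were lower in tip, also when adjusted over the list alone, with a median of -2.78 (adjusted p = 1.32e-25, and adjusted p = 0.151 with an estimated correlation). Of the mesenchymal state list 13 of 14 were lower and 0 higher, also when adjusted over the list alone, with a median of -2.33 (adjusted p = 5.88e-20, and adjusted p = 0.112 with an estimated correlation). It included Vim at -2.01 ± 0.14 (adjusted p = 0.000111), Cdh11 at -3.02 and Tgfbi at -3.32. Of 18 interstitial matrix genes 14 were lower and 0 higher (17 and 0 adjusted over the list alone; median -2.09), with Col1a1 at -3.88 and Col3a1 at -3.04 (adjusted p = 1.52e-20, and adjusted p = 0.0914 with an estimated correlation). Of 13 nephron progenitor genes 11 were lower and 0 higher (12 and 0 adjusted over the list alone; median -1.40), with Itga8 at -2.98 and Eya1 at -2.23 (adjusted p = 3.9e-13, and adjusted p = 0.182 with an estimated correlation). Six2 had a difference of -0.77 ± 0.12 (adjusted p = 0.00593), which did not pass without stalk replicate 1 (adjusted p = 0.0653) or stalk replicate 2 (adjusted p = 0.0792). Beside these, 12 of 15 endothelium genes were lower in tip and 0 higher, also when adjusted over the list alone, with a median of -1.16 and values of -1.86 for Plvap and -1.53 for Tek (adjusted p = 5.72e-12, and adjusted p = 0.112 with an estimated correlation).

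Epithelial genes were somewhat higher in tip than in stalk. Of 27 tight junction and apical polarity genes 13 were higher and 0 lower (18 and 1 adjusted over the list alone; median 0.64), with Rab25 at 1.32 and Cldn3 at 1.18 (adjusted p = 2.25e-06, and adjusted p = 0.21 with an estimated correlation). The higher count was 3 without stalk replicate 1 and 5 without stalk replicate 2, and without tip replicate 1 the lower count was 1. Of 21 adherens junction and desmosome genes 7 were higher and 0 lower (11 and 0 adjusted over the list alone and with the replicate block; median 0.50), with Pkp2 at 1.16 (adjusted p = 5.11e-05, and adjusted p = 0.151 with an estimated correlation). Here the higher count was 4 without stalk replicate 1 and 2 without stalk replicate 2. Cdh1 differed by 0.56 ± 0.15, which did not pass (adjusted p = 0.0574) but did with the replicate block (adjusted p = 0.012), with trend and robust variance (adjusted p = 0.016) and with the mean of its probe sets (adjusted p = 0.0457). Of the 7 keratins and splicing regulators 2 were higher, namely Krt23 (2.20) and Esrp1 (1.47), and 0 were lower, with a median of 0.38. The counts were 5 and 1 adjusted over the list alone, and 3 and 1 with the replicate block. This list was called (adjusted p = 0.0101), and it was not called with an estimated correlation (adjusted p = 0.182) or without tip replicate 1 (adjusted p = 0.0761). Of 18 epithelial transcription factor genes 6 were higher and 1 lower, also when adjusted over the list alone (median 0.42; adjusted p = 0.0038, and adjusted p = 0.21 with an estimated correlation). Grhl2 was 1.12 ± 0.14 higher and Emx2 1.24 ± 0.16 higher, while Gata2 had a difference of -1.90 ± 0.13. Wnt7b did not pass (-0.08 ± 0.14; adjusted p = 0.791).

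Of 15 hypoxia and glycolysis genes 7 were higher in tip and 0 lower (8 and 1 adjusted over the list alone; median 0.41; adjusted p = 0.00774, and adjusted p = 0.21 with an estimated correlation). The higher count was 0 without either stalk array, 3 without tip replicate 1 and 4 without tip replicate 2 or either mesenchyme array, and without tip replicate 2 the lower count was 1. Of 16 immediate early genes 7 were lower and 0 higher (11 and 1 adjusted over the list alone and with the replicate block; median -0.47), with Fos at -1.55 and Klf4 at -1.25 (adjusted p = 2.09e-06, and adjusted p = 0.218 with an estimated correlation). Of 28 cell cycle genes, 0 passed in the limma fit without a block, also when adjusted over the list alone, and 5 were higher and 0 lower at an unadjusted p under 0.05. With the replicate block 5 passed as higher and 0 as lower, among them Plk1 (adjusted p = 0.027) and Cdk1 (adjusted p = 0.032), and with trend and robust variance 9 passed as higher and 0 as lower. Their median was 0.17 and the list was called as higher (adjusted p = 0.0068), but not with an estimated correlation (adjusted p = 0.503), without stalk replicate 2 (adjusted p = 0.0783) or without tip replicate 1 (adjusted p = 0.208). Of 8 erythroid genes 4 were lower and 0 higher, also when adjusted over the list alone (median -0.55), with Hba-x at -1.53 (adjusted p = 0.00192, and adjusted p = 0.168 with an estimated correlation). Without either stalk array 2 erythroid genes were lower. Of 12 myeloid genes 5 were lower and 0 higher, also when adjusted over the list alone (median -0.41; adjusted p = 0.000441, adjusted p = 0.21 with an estimated correlation and adjusted p = 0.165 without the dimmest 40% of genes). The lower count of this list was 2 without stalk replicate 1 and 3 without stalk replicate 2 or tip replicate 1.

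The lists of neurons and neural crest (3 of 11 lower, 0 higher, median -0.08), smooth muscle (2 of 6 lower, 0 higher, median -0.32) and sex-linked genes (1 of 4 lower, 0 higher, median -0.48) were close to the threshold, with the same counts when adjusted over the list alone. With the replicate block the lower counts of these lists were 3, 3 and 2. Their adjusted p was 0.0468, 0.0258 and 0.0468, and with an estimated correlation the adjusted p was 0.222, 0.218 and 0.407. The calls of the neural and smooth muscle lists were lost without stalk replicate 2 (adjusted p = 0.159 and 0.0907) and without tip replicate 1 (adjusted p = 0.31 and 0.186), and that of the neural list with the replicate block (adjusted p = 0.0789). The sex-linked call was lost without stalk replicate 1 (adjusted p = 0.0863), stalk replicate 2 (adjusted p = 0.0553) or tip replicate 2 (adjusted p = 0.319), without the dimmest 40% of genes (adjusted p = 0.134) and with centred arrays (adjusted p = 0.0535). With the mean of all probe sets of a gene none of these 3 lists was called (adjusted p = 0.155, 0.0831 and 0.0834). Their lower counts were 1, 0 and 0 without stalk replicate 1, 2, 0 and 0 without stalk replicate 2, and 2, 1 and 3 without tip replicate 1. The other lists were not called between tip and stalk. For ureteric stalk and urothelium 1 gene was higher and 2 were lower, also when adjusted over the list alone (median 0.22; adjusted p = 0.531), with Shh at -0.97 ± 0.13. Without either stalk array this was 0 and 1, and without either tip array the higher count was 0. For collecting duct transport 0 were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.351), with Hsd11b2 at -1.36 and Fxyd4 at -1.20, and the median of 0.06 and mean of -0.14 differed in sign. Canonical Wnt targets had 3 higher and 2 lower (4 and 3 adjusted over the list alone; median 0.09; adjusted p = 0.551), with Lgr5 at 1.28 and Nkd1 at -1.30. Basement membrane genes had 4 higher and 2 lower (7 and 2 adjusted over the list alone, 8 and 2 with the replicate block; median 0.27; adjusted p = 0.0994), with Lama1 at 1.37 and the nidogen gene Nid1 at -2.32, and their higher count was 2 without either stalk array or tip replicate 1. Early nephron epithelium genes had 1 higher and 4 lower (2 and 4 adjusted over the list alone; median -0.01; adjusted p = 0.0683), and without either stalk array 2 were lower.

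In total 521 genes were higher in tip than in stalk and 1268 lower, so 29.1% of the called genes were higher. With quantile normalization over the 6 tissue arrays this share was 44.0%, from 1250 higher and 1594 lower, and with the replicate block it was 43.2%. The counts were 1623 and 2131 with the replicate block, 205 and 724 without stalk replicate 1, and 197 and 800 without stalk replicate 2.

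**Figure D3:**
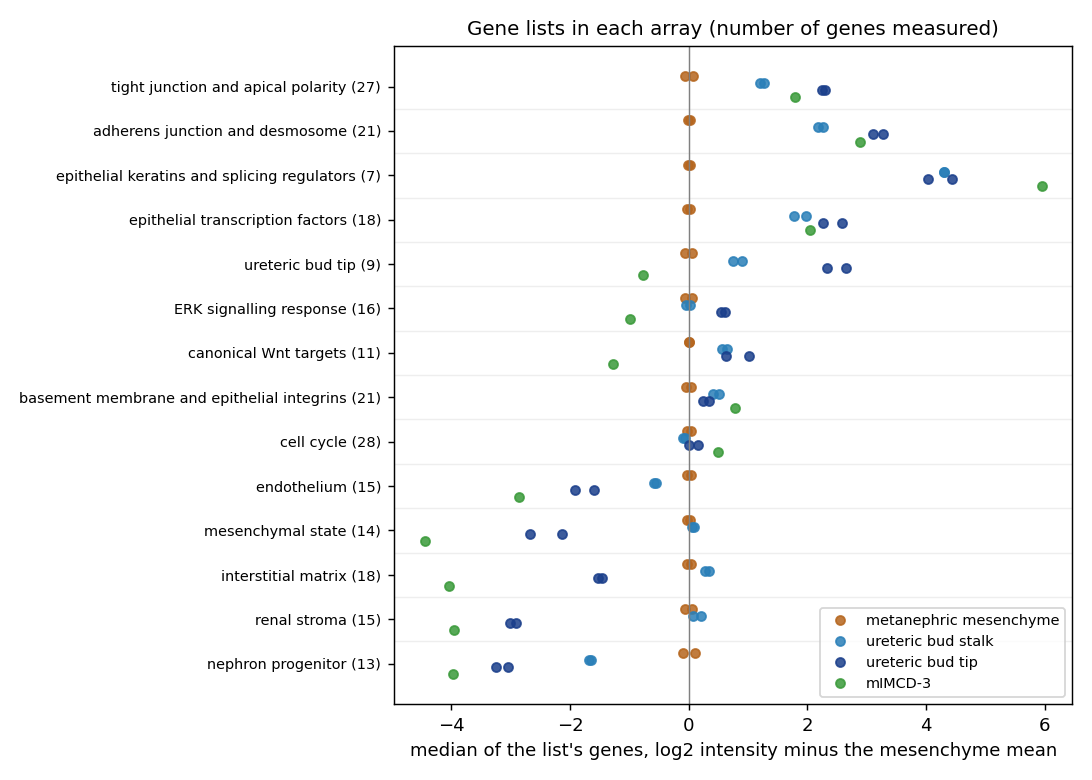
Median log2 intensity of the genes of 14 lists in each array, minus the mesenchyme mean, with 1 point per array and the number of genes measured in parentheses. Renal stroma genes lie at 0.21 and 0.07 in the stalk arrays, at -2.91 and -3.01 in the tip arrays and at -3.95 in mIMCD-3.

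mIMCD-3 cells were set beside the tissues to see which bud genes the cultured collecting duct line expresses. The line has 1 array, so no test was made, and a gene counts as apart only when it lies at least 2 log2 units from the group mean and outside every array of that group. Cdh1 lay at 10.88 in mIMCD-3, against a bud mean of 10.75, and Grhl2 at 10.30 against 9.22. Krt8 lay at 12.31, Esrp1 at 10.47 and Mal2 at 9.89, each within 1 log2 unit of the bud mean. The median of the tight junction list was 0.26 above bud (percentile 90.5 among 10000 random lists of like brightness), that of the adherens junction list 0.13 above (percentile 68.1) and that of keratins and splicing regulators 0.65 above (percentile 95.3). Not every gene of these lists was at the bud level. By the size rule 0 of 27 tight junction genes were higher than in bud and 2 lower. Of 21 adherens junction genes 1 was higher and 1 lower, and of 7 keratins and splicing regulators 3 were higher and 1 lower. Cldn8 and Cldn6 had differences of -5.06 and -6.35 from bud, while Krt19 was 4.89 above it. The epithelial transcription factors had a median of -0.04 (percentile 50.7), with Gata3 at -4.27. By the size rule 3 of these 18 genes were higher than in bud and 5 lower.

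Genes of the bud tip were low in mIMCD-3. Ret lay at 4.12 against 4.78 in mesenchyme and 10.88 in tip, Wnt11 at 6.65 against 10.50 in tip, and Etv5 had a difference of -4.82 from bud. The bud tip list had a median of -2.68 relative to bud, with 7 of 9 genes lower by the size rule and 0 higher, the ERK signalling response list -1.22 with 5 of 16 lower and 1 higher, and the canonical Wnt targets -2.17 with 6 of 11 lower and 0 higher. The medians of these 3 lists lay below all 10000 random lists. Wnt7b, in contrast, lay at 10.93, which is 2.97 above the bud mean. Calb1 lay at 3.38, not above the TrpnX control probe sets of that array (3.46). It had a difference of -9.71 from bud, whose exact size is uncertain at this level. Collecting duct transport genes had a median of -0.59 (percentile 0.41), and ureteric stalk and urothelium genes had one of -0.23 (percentile 21).

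The 4 lists of mesenchymal genes had lower medians in mIMCD-3 than in any tissue group. Vim lay at 4.47, against 12.34 in mesenchyme and 10.30 in tip. Relative to bud, the mesenchymal state list had a median of -3.02, interstitial matrix -2.52, renal stroma -2.32 and nephron progenitors -1.36. Against mesenchyme the same medians were -4.45, -4.03, -3.95 and -3.96. By the size rule 8 of 14, 12 of 18, 9 of 15 and 6 of 13 genes of these lists were lower than in bud, and 11, 13, 11 and 11 were lower than in mesenchyme. The mesenchymal state list had 1 gene higher than in both, S100a4 at 7.85 against 4.54 in mesenchyme and 4.53 in bud, named after its value was seen, and the other lists had 0. Postn at 8.09 and Foxd1 at 9.57 lay above the tip means of 6.16 and 6.38. Endothelium genes had a median of -1.71, erythroid genes -1.10, myeloid genes -0.67, neurons and neural crest -0.76 and smooth muscle -0.45 relative to bud. Basement membrane and epithelial integrin genes had a median of 0.58 above bud (percentile 99.9), with 5 of 21 higher, among them Itga3 at 3.16 above bud, and 5 lower, among them Lama1 at -4.01. Cell cycle genes had a median of 0.49 above bud (percentile 99.99) with 0 of 28 apart by the size rule. Hypoxia and glycolysis genes had a median of 0.09, immediate early genes -0.99 and early nephron epithelium -0.45. The sex-linked list, which joins Xist with Y-linked genes, had one of 1.23.

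By the size rule 394 genes were higher in mIMCD-3 than in bud and 741 lower, and 608 were higher than in mesenchyme and 792 lower. The largest differences to bud were 8.59 for Cryab, which encodes a small heat shock protein, 6.70 for Scel, 6.68 for the interferon-stimulated gene Ifit3, 6.15 for the annexin gene Anxa1 and 6.08 for the cyclooxygenase gene Ptgs2. The lowest were -10.34 for the globin gene Hbb-y, -9.71 for Calb1, -8.76 for the actin-bundling protein gene Fscn1 and -8.15 for Grb10. Calb1 in mIMCD-3 was not above the TrpnX control probe sets of that array, so the size and rank of its difference are uncertain. Grb10 lay close to the lower quartile of the mIMCD-3 array (3.99), and the exact size of its difference is uncertain too. Of the 560 genes at least 1 log2 unit higher in bud than in mesenchyme, 294 (52.5%) were at least 1 log2 unit above both mesenchyme arrays in mIMCD-3, as were 9.88% of all genes. Independent lists would share 55.3 genes. In 20 simulations of unchanged groups 0 genes were shared, but 0 genes passed as higher in bud there, so this value is no measure of the overlap to be had without shared effects. Of the 363 genes lower in bud, 310 (85.4%) were also lower in mIMCD-3, where 8.90% of all genes were, and independent lists would share 32.3. The numbers for independent lists run over all genes, dim ones included, and are not matched on brightness, so they may be too low. Both comparisons use the same mesenchyme arrays, so part of the excess may come from them. With bud set against mesenchyme replicate 1 and mIMCD-3 against replicate 2, 288 of 524 higher genes (55.0%) and 350 of 423 lower genes (82.7%) were shared, where independent lists would share 64.0 and 42.5. With the arrays exchanged, 303 of 586 (51.7%) and 270 of 310 (87.1%) were shared, where independent lists would share 61.0 and 31.9.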

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

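The tests of the stromal pattern and of the mIMCD-3 pattern below were chosen after the results were seen, as was the test of dim probe sets. The test of a brightness trend was set before its result was seen.

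Of the genes called in both stalk and tip against mesenchyme, 74 went in opposite directions, and all of them were called between tip and stalk, which follows from how they were chosen and adds no evidence. They include 70 genes higher in stalk and lower in tip than in mesenchyme. The count was 153 with the replicate block, 24 without stalk replicate 1, 28 without stalk replicate 2, 32 without mesenchyme replicate 1 and 25 without mesenchyme replicate 2. Among the named genes of this kind, the difference of tip from stalk was -5.23 for Plcxd3, -5.18 for Actc1, -5.09 for Tbx18, -5.07 for Sulf1, -4.60 for Postn, -4.42 for Kcnk2, -3.76 for Lum, -3.59 for Zeb2, -3.51 for Synpo, -2.50 for Sfrp2, -2.50 for Nid2 and -2.06 for Isl1. Not every probe set of Sulf1, Zeb2 and Synpo had this sign. In the other direction, Etv4 was 2.04 higher in tip than in stalk, with -0.61 in stalk and 1.43 in tip against mesenchyme.

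Tip and stalk also differed in their difference from mesenchyme for 19 lists, by the test of tip against stalk at the preset correlation, and for 0 lists with an estimated correlation. The list medians of tip minus stalk were -2.78 for renal stroma, -2.33 for mesenchymal state, -2.09 for interstitial matrix, -1.40 for nephron progenitor, -1.16 for endothelium, -0.55 for erythroid cells, -0.48 for sex-linked genes, -0.47 for immediate early genes, -0.41 for myeloid cells, -0.32 for smooth muscle and -0.083 for neurons and neural crest. They were 1.92 for ureteric bud tip, 0.76 for ERK signalling response, 0.64 for tight junction and apical polarity, 0.50 for adherens junction and desmosome, 0.42 for epithelial transcription factors, 0.41 for hypoxia and glycolysis, 0.38 for epithelial keratins and splicing regulators and 0.17 for cell cycle.

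Stroma and matrix genes lay near the mesenchyme level in the stalk arrays. Mesenchyme tissue mixed into the stalk samples would bring progenitor and stroma transcripts in 1 ratio, yet on the linear scale the stalk stood at a median 0.86 of the way from tip to mesenchyme for 13 stroma genes and at 0.21 for 12 progenitor genes (difference 0.651, and 0.528 to 0.837 over the 8 combinations of single arrays; quartiles 0.52 to 1.42 and 0.15 to 0.32). For 12 interstitial matrix genes the median was 1.36 (lowest 0.28, highest 2.13), and a mixture of tip and mesenchyme tissue could not give a value above 1. These values argue against such a mixture as the whole cause, though not against a smaller share. Cdh1, which in the lowest stalk array was 6.45 above the highest mesenchyme array, argues against exchanged labels. Stromal cells of another makeup, carried along with the stalk, may account for part of the pattern. The 43 junction and keratin genes higher in bud had a median stalk to tip ratio of 0.642 (quartiles 0.53 to 0.78, 38 under 1). Dilution alone would give 1 ratio for all, and 5 genes lay above 1, up to 1.41 for Cldn1. This ratio restates the tip against stalk difference of these lists. A higher level of these genes in tip epithelium would give it too, so it cannot decide between them. Median shares found in the same way were 0.51 for 12 endothelium genes (lowest 0.36, highest 0.68), 0.33 for 6 myeloid and 0.32 for 4 erythroid genes. For 4 neural genes the share was 0.16 (0.02 to 1.97). All shares used genes at least 1 log2 unit brighter in mesenchyme than in tip. Endothelial and blood cell markers were thus higher in stalk than in tip samples, which does not tell where the stroma genes were expressed. Another level of the junction and keratin genes in stalk epithelium, and expression of stroma genes by stalk tissue itself, were not tested and stay open.

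The mIMCD-3 array had the medians of the junction lists near the bud level, with single genes far from it on both sides, and a median of bud tip genes of -2.68 relative to bud. In the normalized values, 9294 genes outside the lists at the same bud levels as the tip genes had a median of 0.0498 above bud (quartiles -0.46 to 0.61). The low values of the tip genes were thus not shared by most genes of like level. Whether the raw signal of that array was weaker cannot be decided from these values, because RMA equalises the signal distributions between arrays. A difference between the later array and the earlier arrays cannot be told apart from the cell line, because the later batch holds no tissue. The highest correlation of mIMCD-3 with a tissue array was 0.922, against a lowest value of 0.960 between tissue arrays. A difference in biology between the cell line and the embryonic bud stays open and was not tested.

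Arrays with the same replicate number deviated together from their group means. The quartiles of the replicate 2 arrays lay closer together in each tissue, but a brightness trend is argued against as the whole cause, since the lowest of the 3 correlations was 0.305 after the trend was removed in 100 bins of brightness. Noise of dim probe sets is argued against by the brightest probe sets, among which the lowest correlation was 0.427. A shared day of dissection or hybridisation, or a shared litter, may underlie the pattern and was not tested, since the labels give none.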

How the results depend on the processing

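The tests of other settings for the 74 genes of opposite direction, for the list members called and for separate mesenchyme arrays in the mIMCD-3 overlap were chosen after the results were seen, and all other settings were planned. Of 270 results for named genes, 221 kept their direction and their side of the threshold under the mean of all probe sets, the omission of probe sets by name, centring, trend and robust variance, the block and the omission of each array, the settings run for single genes. Of 48 list results 40 did so under the settings run for lists apart from the estimated correlation, and no result reversed. Apart from the genes fixed by name, the named genes were chosen by the size of their differences in these same data. Their share is therefore no measure for all called genes. With the mean of all probe sets, 1753 of the 2018 genes called for bud against mesenchyme kept their call. For stalk and for tip against mesenchyme 825 of 1007 and 2493 of 2865 did, and for tip against stalk 1505 of 1789. The fit that treats every probe set on its own, which tests more features and can count a gene more than once by its probe sets, gave 1762 higher and 1390 lower probe sets for bud against mesenchyme, 2154 and 2487 for tip against mesenchyme, and 2054 lower for tip against stalk. The replicate block gave 1552 lower for bud against mesenchyme, 1231 and 577 for stalk against mesenchyme, 2037 and 2331 for tip against mesenchyme, and 1623 and 2131 for tip against stalk. The genes called without the block were all called with it, 2018, 1007, 2865 and 1789 in the 4 contrasts. The block moved 15 named gene results past the threshold and ended 1 list call (neurons and neural crest, tip against stalk), and it changed no other call of a named gene or list. The stricter rule of at least 1 log2 unit left 560 and 363 genes for bud, 481 and 100 for stalk and 693 and 804 for tip against mesenchyme, and 162 and 725 for tip against stalk. Trend and robust variance gave 354 lower for stalk against mesenchyme and 890 higher for tip against stalk. Quantile normalization over the 6 tissue arrays gave 354 lower for stalk against mesenchyme and 1250 higher for tip against stalk. With an estimated correlation 2 of 21 lists stayed called for bud against mesenchyme and 0 of 19 for tip against stalk. That setting also missed the simulated raised list in every contrast except bud against mesenchyme. For mIMCD-3, a smaller step of 1 log2 unit gave 2045 higher and 1780 lower than mesenchyme and 1766 and 1686 than bud. Leaving out the dimmest 40% of genes left 255 higher than bud. At 2 log2 units on both sides, which is stricter, 100 genes were shared between bud and mIMCD-3. Leaving out each array in turn gave 725 to 1363 higher and 475 to 1191 lower genes for bud against mesenchyme, 427 to 922 and 92 to 316 for stalk against mesenchyme, 987 to 1927 lower for tip against mesenchyme, and 197 to 769 and 724 to 1789 for tip against stalk. A group left with 1 array was assumed to vary like the others. Leaving out an array also lowers the precision of contrasts with its group, and how much of the changes came from this was not measured. Except for the fewer or more features tested and the stricter or looser thresholds, the cause was not tested. Over all arrays left out in turn, 1620 named gene results and 288 list results were compared, called or not, and 64 and 10 calls ended while 7 and 1 were added. Centring added 3 gene calls and ended 1 list call, trend and robust variance added 10 and ended 1 gene call, the mean of all probe sets ended 8 and added 2 gene calls and ended 3 list calls, leaving out the dimmest genes ended 3 list calls, and leaving out probe sets by name ended 2 gene calls. RMA values give no background level, so the signal over background was not measured and small folds of dim genes stay uncertain.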

Other observations

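The lists of this part, and the genes named in it, were chosen after their values were seen. Genes of retinoic acid synthesis were split between the tissues. Aldh1a2 had a difference of -1.89 between bud and mesenchyme, and Rdh10 one of -1.13, while Aldh1a1 was 4.93 higher and Aldh1a3 2.06 higher in bud. Of 15 measured genes of retinoic acid synthesis, binding and response, 2 were higher in bud and 4 lower, and between tip and stalk 3 were higher and 4 lower. Among 21 Wnt ligands and R-spondins, 5 were higher in bud and 3 lower. Wnt6, Wnt9b and Wnt11 were 1.61, 3.05 and 1.90 higher in bud and Rspo1 and Rspo3 lower, and mIMCD-3 had Wnt10a at 7.65 and Wnt7b at 10.93. Shh, the hedgehog ligand gene, was 2.26 higher in bud and lower in tip than in stalk (-0.97). Its target genes Gli1 and Ptch1 were lower in tip than in stalk as well (-1.96 and -1.53), and so were Bmp4 (-2.70), Bmp5 (-1.38) and the BMP target gene Id1 (-1.16), while Bmp7 was 1.08 higher in tip. In all, 9 of 19 genes of BMP and hedgehog signalling were lower in tip than in stalk and 1 was higher. Gli1, Bmp4 and Bmp5 were among the genes higher in stalk and lower in tip than in mesenchyme, as were stromal markers, and all 15 renal stroma genes were lower in tip than in stalk with a median of -2.78. A change of signalling was therefore not separated from the stromal pattern.

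Of 21 imprinted genes measured, 10 were lower in mIMCD-3 than in bud by the size rule and 0 higher, with a median of -1.50. Mest lay at 6.61 against a mesenchyme mean of 13.03, Peg3 at 4.88 against 12.54, Igf2 at 6.89 against 13.02 and Grb10 at 4.02 against 12.47. Between bud and mesenchyme, 8 of the 21 were lower in bud and 1 was higher, with -1.64 for Dlk1 and -1.32 for Meg3. Interferon-stimulated genes went the other way in mIMCD-3. Of 19 measured, 12 were higher than in bud by the size rule and 0 lower, with a median of 2.22, among them Ifit3 at 11.53 and Ifit1 at 8.30 against tip means of 4.89 and 3.71. No explanation was tested for either group. Of the sex-linked genes, Xist lay at 5.63 in mIMCD-3 against 11.05 in mesenchyme, and the Y-linked gene Kdm5d at 8.63 against 7.12.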
